A study of Strongylocentrotus purpuratus with 2 samples.

How the data were processed

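Chromatin immunoprecipitation followed by sequencing (ChIP-seq) measures which stretches of DNA are recovered with an antibody against a protein. Embryos of the purple sea urchin, Strongylocentrotus purpuratus, were taken at the mesenchyme blastula stage, 24 hours after fertilisation. Chromatin from 3 cultures was used, per the series' design text. A custom antibody against Alx1 gave the ChIP library, and normal rabbit IgG gave the mock library. Per the sample labels each library is pooled, so the series holds 2 libraries, 1 per antibody, sequenced as single 50-nt reads. No difference between them has a replicate check, and no spread between cultures can be given.

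The deposited data are 1 peak list and 1 list of summits, called on the pooled libraries. Trimmomatic, Bowtie2, SAMtools and MACS2 are named, without versions, in the submitters' processing notes. Their settings are not given in the labels, and the genome build is not given in the sources used here. The p threshold was taken as 0.005, which is carried in the name of the deposited list and lies just above its largest p of 0.00498. Each row of the peak list holds, as deposited by the authors, a fold enrichment of ChIP over local background at the summit, a −log10 p and a −log10 q of the peak caller. The deposited whole-number score equalled the integer part of 10 times the −log10 p in 2906 of 2906 rows, and was not used further. Positions are in bp on the authors' scaffolds and are printed here counting from 1. The 2906 summits of the summit list were identical in position to those of the peak list. These per-peak values are the authors' throughout and were used to describe, rank and filter peaks within the list.

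The only gene table at hand was for the Spur_5.0 assembly, and 0 of the 2906 peaks lay on a scaffold named in it. Distances to genes, genomic classes, motifs at summits, and the lists of skeletogenic, mesodermal, endodermal, ectodermal, neural and housekeeping genes fixed before the data were examined were therefore not analysed here. Peaks are named by scaffold and position, under a rule set before the data were examined: the 10 peaks with the highest deposited fold enrichment. The runs of 4 or more summits, the peaks with the most ChIP fragments and the peak with the highest mock value were chosen after their values were seen.

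Library totals were not used here, and the total depth is unknown. The number of fragments at each summit was instead solved from the deposited fold enrichment and −log10 p. MACS2 extends each read to the fragment length, scales the larger library down, and takes as background the highest of the genome-wide mock level and the mock level at the summit, over 1 kb and over 10 kb. Its fold is (scaled ChIP + 1) / (mock + 1), and its p is the upper Poisson tail of the scaled ChIP value at that background. For each peak the whole number of ChIP fragments that met both values was sought, with 1 scale for the whole list fitted on 300 peaks drawn at random. The fitted scale on the ChIP library was 0.876. All 2906 peaks were solved with a misfit in −log10 p of at most 3.46e-05, whereas the next-best whole number missed by at least 0.000232. The recovered mock backgrounds were whole numbers, whole steps of the 1 kb or 10 kb average for a fragment length of 190 bp, or the genome-wide level of 1.76 fragments, within 0.0003, for all 2906 peaks. The narrowest peaks were also 190 bp wide. On 1000 simulated summits the procedure recovered the ChIP count and the background of 100% of them. These were simulated with the same formulas, at a scale of 0.8 and without backgrounds in 10 kb steps. The simulation therefore checks the solving and not the formulas, which the labels do not state.

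Intervals on fragment numbers are exact 95% Poisson intervals. Intervals on the ratio of scaled ChIP to mock are exact 95% intervals (Clopper-Pearson, given the sum of both counts). Both cover counting error only, and the treatment of duplicate reads is not given in the sources used here. Neither allows for the summit being the point of highest coverage, or for peaks named because their fold or count was highest. Such a choice tends to raise the ChIP count and the ratio. At the median of 18 ChIP fragments the interval runs from 10.7 to 28.4, and it is wider, relative to the value, at weaker peaks.

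Spacing of summits was compared with 1000 random layouts, in which each summit was redrawn evenly between the first base of its scaffold and the end of the last peak on it. Scaffold lengths, assembly gaps and mappability were not used. The permutation tests are two-sided, and 0.002 is the smallest p that 1000 layouts can give. Of 20 simulated even layouts, 0 passed the permutation test at 0.05, and a layout with some summits moved near others gave p = 0.002 in the permutation test. These were drawn over the same extents as the random layouts. They check the procedure and not the extents, gaps or mappability. Medians of summits with and without a close neighbour were compared by permutation with 100000 resamples, and the likeness of neighbouring summits by 10000 shuffles of the values over all peaks, with Benjamini-Hochberg adjustment over the 12 combinations of measure and distance. The share of summits with a close neighbour was compared over 5 equal parts of the list by fold with 10000 shuffles, a test chosen after the shares were seen. Peaks are not replicates of the experiment, so these tests describe this list.

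Alternatives set before the data were examined were a −log10 p of at least 5, a q of at most 0.05, 1 summit per region, and 20 kb in place of 5 kb. The q limit was set for the number of peaks alone. Uses of these limits on summit position and mock values, and that of the q limit on spacing, were chosen after seeing the data. Further alternatives chosen after seeing the data took the widest peaks, merged close summits, enlarged the scaffold extents, kept peaks with low mock values, left out the pseudocount, or counted the error of the mock library as well. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.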

Results

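To locate the DNA bound by Alx1 at the mesenchyme blastula stage, chromatin recovered with an Alx1 antibody was compared with chromatin recovered with normal rabbit IgG. Alx1 is a homeodomain transcription factor required for the skeletogenic primary mesenchyme cells, which enter the blastocoel at about this stage and build the larval skeleton. Both libraries came from whole embryos. Each antibody had 1 library, pooled from 3 cultures, so every difference below is between 2 libraries and has no replicate check.

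The deposited list held 2906 Alx1 peaks on 1263 scaffolds. The median peak was 222 bp wide, with quartiles of 197 and 272 bp and a maximum of 894 bp. At 497 peaks (17.1%) the width was 190 bp, the narrowest in the list. No peak overlapped another, and none was listed with more than 1 summit. Summits lay near the middle of the peaks, at a median of 49.2% of the width, with quartiles of 35.8% and 62.7%. In 78.3% of peaks the summit lay in the middle 50% of the width.

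The median fold enrichment was 3.38, with quartiles of 2.88 and 3.97, and 247 peaks (8.50%) reached 5-fold. Only 6 peaks reached 10-fold. The largest p in the list was 0.00498, and 1671 peaks (57.5%) had a −log10 p of at least 5. After the peak caller's own correction, 1884 peaks (64.8%) had a q of at most 0.05 and 1397 (48.1%) a q of at most 0.01. The remaining 1022 peaks (35.2%) had a q above 0.05, and their median fold was 2.92, against 3.77 in peaks with a q of at most 0.05.

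The highest fold enrichment, 12.9, was found on Scaffold180 at 327556 to 327940, a peak of 385 bp. This site also had the highest −log10 p in the list, 90.55. Its summit was covered by 134 ChIP fragments (95% Poisson interval 112 to 159), against a mock background of 8.17 fragments, and the ratio of scaled ChIP to mock was 14.4 (interval 10.1 to 20.8). The next sites were Scaffold1191 at 3194 to 3538, with a fold of 12.6, and Scaffold21 at 855952 to 856303, with a fold of 12.4. Scaffold122 at 935501 to 935738 followed with a fold of 12.3. The ratios without the pseudocount at these 3 sites were higher than on Scaffold180: 15.5 (interval 5.81 to 58.6) on Scaffold1191, 16.1 (interval 9.13 to 30.1) on Scaffold21, the highest in the list, and 15.1 (interval 5.64 to 57.0) on Scaffold122. The mock values matched 4 fragments on the summit itself on Scaffold1191 and on Scaffold122. On Scaffold180 and Scaffold21 they matched 43 and 16 fragments over 1 kb, so the ratios rest on unlike windows. Because these intervals overlap, the order of the top 4 sites could not be told at this depth.

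The remaining peaks among the first 10 had folds between 9.56 and 10.7. In falling order they lay on Scaffold127 at 175744 to 176131, Scaffold2283 at 44828 to 45183, Scaffold6 at 402832 to 403042, Scaffold4370 at 8542 to 8851, Scaffold38 at 995823 to 996246 and Scaffold113 at 1129957 to 1130287. Fragment numbers at these 6 summits ranged widely. The Scaffold6 summit carried 31 ChIP fragments (interval 21.1 to 44.0) and the Scaffold113 summit 108 (interval 88.6 to 130). The genome build is not given in the sources used here, so genes, exons or introns at these positions were not analysed here.

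Across the list, summits were covered by a median of 18 ChIP fragments, with quartiles of 12 and 27 and a range of 7 to 169. The mock background at the same positions had a median of 4 fragments, with quartiles of 2.28 and 6, where the genome-wide mock level of 1.76 is by construction the lowest value it can take. Without the pseudocount, the median ratio of scaled ChIP to mock was 4.16, with quartiles of 3.31 and 5.04. The background matched mock fragments on the summit itself at 1631 peaks (56.1%) and the genome-wide level at 215 (7.40%). It matched whole steps of the 1 kb average at 700 (24.1%) and only those of the 10 kb average at 360 (12.4%). Every whole step of the 1 kb average is also one of the 10 kb average. Some of the 700 may therefore have been set over 10 kb, and their ratio intervals take the 1 kb window.

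**Figure D1:**
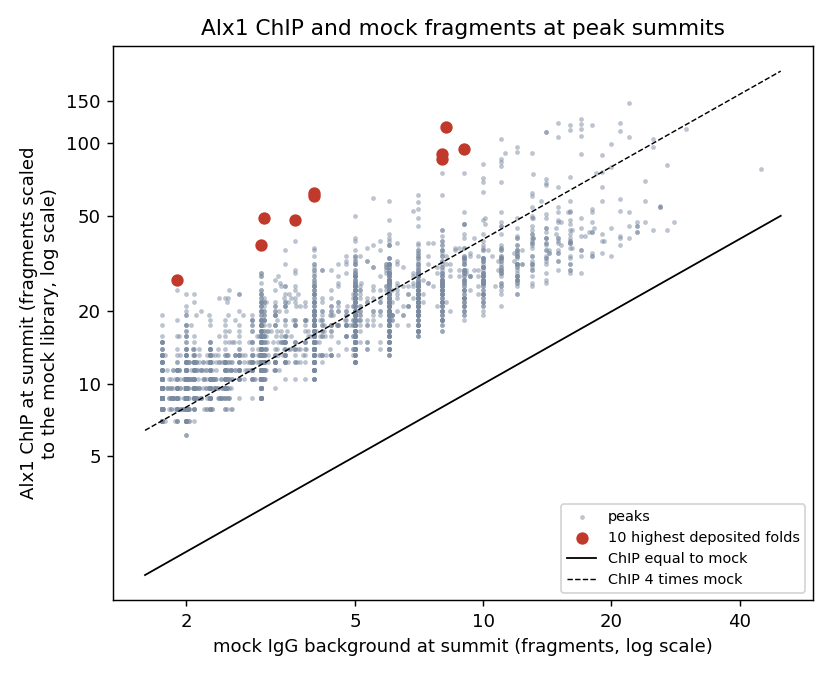
Alx1 ChIP fragments at each summit, scaled to the mock library, against the mock IgG background at the same position, both in fragments on log axes. Each grey point is 1 of 2906 peaks, red points are the 10 peaks with the highest deposited fold, and the lines mark equal and 4-fold values. Every peak lies above the line of equality, and the red points lie at mock values from 1.90 to 9.

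Called sites with more mock fragments had more ChIP fragments and lower ratios, both of which the calling itself partly fixes. At the 215 peaks with the background at the genome-wide level, the median was 11 ChIP fragments and the median ratio 5.48 (quartiles 4.99 and 5.98). At the 393 peaks with a mock background from 8 to under 16, the medians were 36 fragments and a ratio of 2.98 (quartiles 2.48 and 3.50). At the 84 peaks with 16 or more, they were 53.5 fragments and 2.43 (upper quartile 3.50). The p threshold of 0.005 asks for more fragments where the mock is higher: the smallest ChIP count that passes at the median mock level was 7, 22 and 36 fragments in these 3 sets. Those counts correspond to smallest passing ratios of 3.49, 1.93 and 1.66, and the mock value is also the denominator of the ratio. No relation beyond the calling was tested.

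The order of the strongest sites depended in part on the measure. Of the 10 peaks first by fold, 3 were also among the first 10 by p, and of the first 100 by fold, 60 were among the first 100 by p. The first 10 by fold had a median mock background of 4 fragments and the first 10 by p of 14. The site second by p, on Scaffold945 at 97906 to 98363, had the most ChIP fragments in the list, 169 (interval 144 to 196), on 22 mock fragments and with a fold of 6.48. At the summit with the highest mock value, on Scaffold2527 at 2145 to 2418, 45 mock fragments stood against 89 ChIP fragments, a ratio of 1.73 (interval 1.20 to 2.54).

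Alx1 summits lay closer together than positions drawn evenly on the same scaffolds, with any gaps and unmappable sequence included. A neighbouring summit within 5 kb was found for 455 summits (15.7%), against a mean of 7.50% in 1000 random layouts, of which the middle 95% ran from 6.19% to 8.74% (permutation test, p = 0.002). The excess was greatest at short range. Consecutive summits under 1 kb apart numbered 74, against 24.7 expected, and those from 1 to 2 kb apart 66, against 23.4. From 2 to 5 kb there were 108 pairs against 64.8, and from 5 to 10 kb 129 against 98.0. From 10 to 20 kb the observed 160 pairs lay within the random range of 144 to 190.

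**Figure D2:**
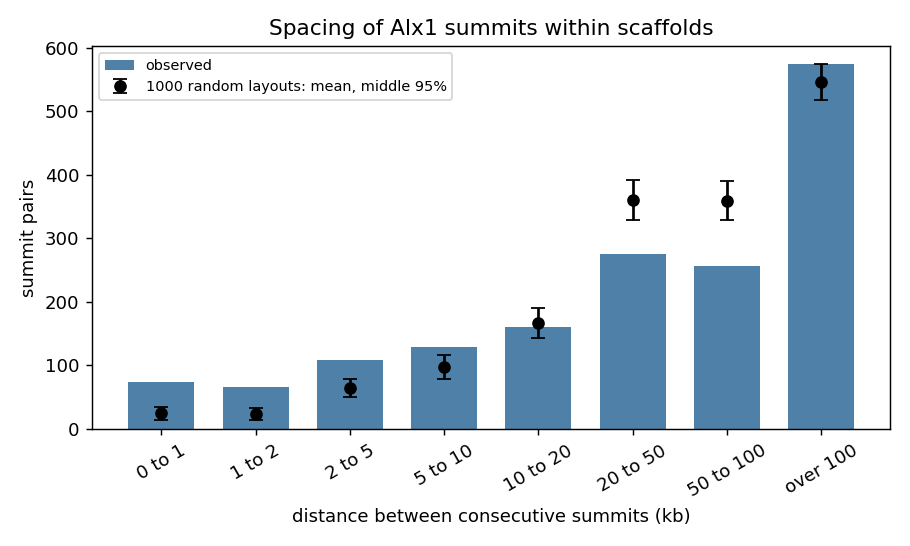
Number of pairs of consecutive Alx1 summits by the distance between them in kb. Bars are the observed pairs, and points with error bars are the mean and the middle 95% of 1000 random layouts on the same scaffolds. The bars exceed the random range in the 4 classes up to 10 kb, and fall below it from 20 to 100 kb.

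Linking summits within 5 kb of the next gave 207 runs of 2 or more summits and 38 runs of 3 or more. Random layouts gave a mean of 7.24 runs of 3 or more and at most 16 (permutation test, p = 0.002). The longest run held 5 summits over 9.03 kb of Scaffold1985, from 126401 to 135432, with folds from 2.31 to 5.42. A run this long is not outside the random layouts, whose longest held 6. The only other run of more than 3 lay on Scaffold122, with 4 summits from 931069 to 940820. It included the peak at 935501 to 935738 with a fold of 12.3, and its other summits had folds of 6.17, 4.05 and 4.71.

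**Figure D3:**
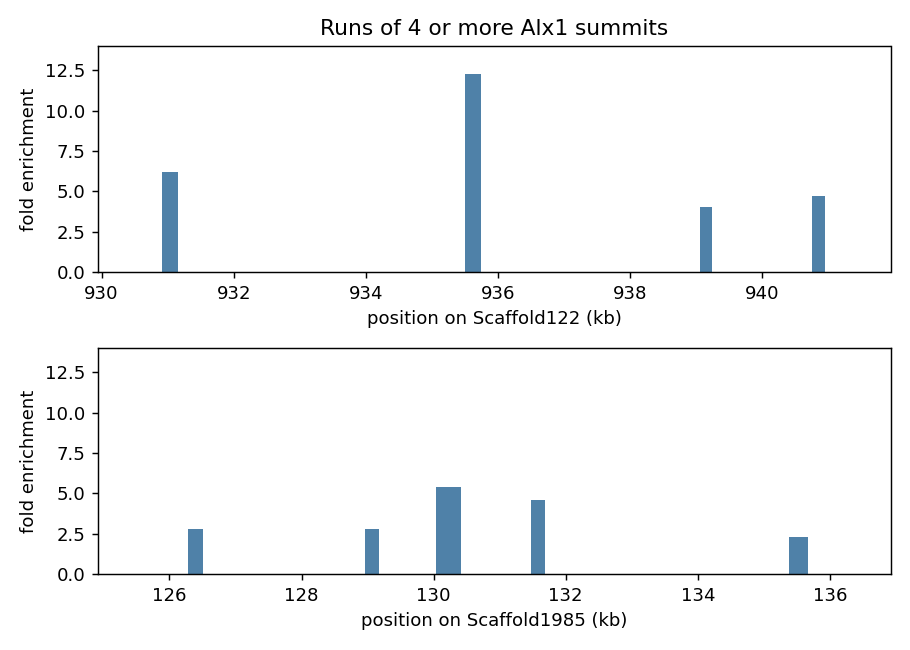
Positions in kb of the peaks in the runs of 4 or more Alx1 summits, on Scaffold122 with 4 and on Scaffold1985 with 5. Each bar spans a peak to scale, and its height is the deposited fold enrichment. The highest bar on Scaffold122 reaches 12.3 and the highest on Scaffold1985 reaches 5.42.

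Summits with a close neighbour carried more ChIP and more mock fragments than the others. The median fold was 3.43 for the 455 summits with a neighbour within 5 kb and 3.36 for the other 2451, a difference that did not pass the test (permutation test, p = 0.163, adjusted p = 0.163 over 3 measures). The upper quartiles were 4.22 and 3.91. The share of summits with a close neighbour differed over 5 equal parts of the list ranked by fold (permutation test, p = 0.0002). From the lowest folds to the highest it was 16.5%, 16.01%, 10.8%, 14.3% and 20.7%. Median ChIP fragments were 22 and 17, and median mock backgrounds 5 and 3.48. Both differences in fragments passed (permutation test, p = 1e-05 each, the smallest the resampling can give, adjusted p = 1.5e-05). Single summits were shuffled in these tests and in that of the 5 parts. Neighbours within 5 kb are alike, however (Spearman rho 0.18 for fold, 0.36 for ChIP and 0.44 for mock values), so these p-values are probably too small. The p threshold also asks for more ChIP fragments where the mock is higher, and this was not separated here.

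Peaks were spread over many scaffolds. A single peak was found on 636 scaffolds, 5 or more on 149 and 10 or more on 15. The most, 14, were found on Scaffold5, over 1958 kb, and on Scaffold58, over 543 kb. On Scaffold1985, 11 summits lay within 107 kb. Scaffold lengths were not used here, so these numbers are not densities.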

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

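Of 2906 peaks, 1671 remained at a −log10 p of at least 5, 1884 at a q of at most 0.05 and 2906 with 1 summit per region. The last number could not differ, because no peak was listed with more than 1 summit. Chosen after seeing the data, a test that also counts the error of the mock library left 2101 peaks at p of at most 0.005. It kept 840 of the 1631 peaks whose background came from the summit itself and 1261 of the other 1275. The other 1275 include the 215 at the genome-wide level, for which no mock error was counted. At the 1631 peaks the summit value was the highest of the mock levels compared, with a median of 5 fragments. Part of the loss there follows from that choice of background and was not separated. Closeness of summits kept its direction and passed the permutation test under all 7 alternatives run, with observed shares of 1.33 to 2.55 times the random mean. The lowest ratio came with 20 kb in place of 5 kb (31.5% against 23.7%), and the highest with enlarged scaffold extents (15.7% against 6.15%). Enlarging leaves the observed share as it was and can only raise the ratio, so passing there is no support. No alternative left out gaps or unmappable sequence, which would narrow the extents. The share of peaks with a mock background of at least 8 was 16.4% in the whole list, 21.2% at a −log10 p of at least 5 and 19.4% at a q of at most 0.05. At a given ratio more fragments give a smaller p, so such limits favour high-mock peaks. The median −log10 p was 4.80 at the genome-wide mock level and 6.98 at a mock from 8 to under 16. The median summit position stayed between 49.2% and 49.4% of the width in strong and in wide peaks. The peak with the highest fold, 12.9, had a ratio of 14.4 without the pseudocount, where the highest ratio of any peak was 16.1, and 7 of the first 10 peaks by fold, and 81 of the first 100, were also among as many first by that ratio. Alternatives set beforehand on genomic classes, distances to genes, motifs and gene lists were not run, because no genome or annotation of the files' build was at hand. No paired analysis was possible because each antibody had 1 pooled library, and no library could be left out. Fragment numbers limit the ranking of single sites and the calls with low counts.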

Other observations

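Peaks with 100 or more ChIP fragments numbered 29, on 27 scaffolds, and 9 of them were among the 29 peaks first by fold. Their median fold was 6.74, their median width 351 bp and their median mock background 17 fragments. Peaks with 60 to 79 ChIP fragments numbered 31, those with 80 to 99 numbered 17, with 100 to 119 numbered 12, with 120 to 139 numbered 15, with 140 to 159 numbered 1 and with 160 to 179 numbered 1.

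All tests below were chosen after the peak list had been examined; those of high mock values, of random sets of peaks, the bootstrap interval and the lists of equal length were chosen after the results they bear on were seen.

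Mock fragments were high at many Alx1 summits: 477 peaks (16.4%, Wilson interval 15.1% to 17.8%) had a mock background of at least 8 fragments, 4.55 times the genome-wide level. The interval takes peaks as independent, although close neighbours were alike in mock values, and it covers no spread between cultures. Counting scatter of a mock library even at that level gives 1.40 summits with 8 or more mock fragments on them, and at least 415 were found. Only summits that set their own background are counted in the 415. The genome-wide level is the peak caller's, its settings are not given, and an uneven mock library is not judged by this count. Mock standing evenly at 8 or more over 10 kb, as over a long collapsed repeat, would show in the 10 kb average. In simulated flat regions at such levels, that average was the highest at 21.4% or more of positions. A broad rise with a higher point at the called summit was not simulated, so the limits below do not judge it. In the list 0 of 477 matched the 10 kb average alone, which allows up to 0.629%. Among the 477, 62 matched the 1 kb average, and any of them set over 10 kb is not counted in that limit. If every region stood at 8, a milder rise over 10 kb with counting scatter gives at most 23.9 summits with 16 or more mock fragments. By the same limit up to 14 peaks could lie in flat regions above that, and at least 77 such summits were found. For the 338 summits with 8 to 15 mock fragments this milder rise cannot be told apart from a local one, and recovery of open chromatin by IgG or short repeated sequence may account for a local rise, which no genome sequence was at hand to test.

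The closeness of summits to one another was weighed against 2 technical explanations. Another could not be judged: random layouts may place summits in gaps or unmappable sequence, where no peak is called. That can lower the random share in every set compared here. Splitting of single bound regions into calls under 1 kb apart is argued against as the whole cause. After merging such summits, 11.5% still had a neighbour within 5 kb, above the highest of 1000 random layouts (8.97%). Splitting into calls further apart cannot be judged, because the merging leaves pairs from 1 to 5 kb apart as they were. Sites rich in mock fragments remain open as part of the pattern. Among the 1456 peaks with mock at or under the median the share was 5.91%, above the random mean of 3.67% (permutation test, p = 0.004) but under the highest layout, 6.18%, and among the other 1450 it was 14.3% against 5.72%. Of 1000 random sets of 1456 peaks, with a mean share of 8.64%, 1 had a share as low as the low-mock set (permutation test, p = 0.004), and no biological explanation was tested.

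A hypothesis that neighbouring Alx1 sites have similar strength was tested on the same list. Fold enrichment of consecutive summits within 5 kb was correlated across 248 pairs (Spearman rho 0.18, permutation p = 0.0046, adjusted p = 0.0138). At 5 to 20 kb rho was 0.02 (adjusted permutation p = 0.749) and at 20 to 100 kb 0.08 (adjusted permutation p = 0.0661), and the ratio without the pseudocount gave rho 0.24, -0.01 and 0.10 at the 3 distances (adjusted permutation p = 0.0004, 0.915 and 0.0353). ChIP fragments passed at each distance, with rho 0.36, 0.15 and 0.11 (adjusted permutation p = 0.0004, 0.0178 and 0.0213), and mock values at 0 to 5 kb (rho 0.44, adjusted permutation p = 0.0004) and 20 to 100 kb (rho 0.11, adjusted permutation p = 0.0178), although mock windows of up to 10 kb overlap between close neighbours. For pairs 1 to 5 kb apart rho was 0.1631 over 174 pairs (permutation p = 0.0296, not adjusted). This argues only weakly against splitting of 1 region into calls under 1 kb apart as the whole cause. A mock level shared by neighbours stays open: with fold ranked within 20 mock levels rho was 0.1132 (permutation p = 0.0749, bootstrap 95% interval -0.02 to 0.23, which includes 0.18), and in the low-mock set it was 0.17 over 45 pairs (permutation p = 0.258).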
